A study of Mus musculus with 24 samples.

How the data were processed

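The 24 heart samples of male mice, 14 weeks old and fed chow, gave 1 library each, and the labels put them in 6 genotypes of Acadl and Acadvl on a mixed strain background. No label says that the samples came from separate mice, so p-values measure only the spread between these samples. Per the labels' protocols, RNA was isolated with QIAzol and RNeasy columns and libraries were made by polyA capture and sequenced as single-end reads on an Illumina HiSeq. The labels give 2 RNA isolation batches, of 9 and 15 libraries, and the file headers show 2 processing runs that match them. Libraries were numbered within each genotype in accession order, so these numbers pair nothing. Part of each title is a number that some libraries share, and its meaning is not given in the sources used here.

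The deposited values are raw read counts per gene symbol, 1 file per library, over 24421 genes. Per the file headers, reads overlapping exons were counted per gene with featureCounts 1.5.2 on UCSC mm10 genes, with primary alignments only, without regard to strand, and with a read that overlaps several genes counted for each. The submitters' processing notes name STAR 2.5.1b and featureCounts 1.5.3, and the builds mm10 and GRCm38. The deposited table of the whole series held the same counts, with 0 cells that differed and 26 gene symbols altered, and was used for that comparison only. Counting without strand cannot tell a gene from an antisense partner, and overlapping genes share reads: Mir324 lies inside Acadvl. Genes with close copies (Mup, Ifit, Acot, Gsta and Slfn families) can take or lose reads of their relatives, so their values are uncertain. The files hold 0 mitochondrially encoded genes, and 153 genes had no single locus and were left out of tests by position. Positions are those given in the count files (mm10), counted from 1.

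Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr on the 6 genotypes, which left 15804, libraries were scaled by TMM factors, and all 24 libraries entered 1 quasi-likelihood fit (glmQLFit with legacy off and robust on) with genotype and RNA isolation batch as terms. Each two-sided test was adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are on the log2 scale with standard errors from the F statistic, and levels are in CPM with TMM factors, as mean ± SD. The 7 comparisons were libraries labelled Acadl KO against wild type, the same label against Acadl Het, Acadl Het against wild type, Acadvl Het against Acadvl wt, Acadvl KO against Acadvl wt, Acadl KO against Acadvl KO, and the interaction of Acadl KO with Acadvl Het. The comparisons, tests, alternatives, 37 gene lists and rule for naming genes were fixed before the data were examined. Some lists were chosen to fit the series title, which names the integrated stress response and tRNA charging. Lists on these topics are therefore not independent of what the submitters reported.

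The fixed lists were tested on log2 CPM from limma voom, with camera of limma 3.58.1 at a preset correlation between genes of 0.01. They were also tested with an estimated correlation, and with fry. A further 7 lists were written after the values were seen: ribosome assembly in the nucleolus, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, translation factors, cardiac ion channels and receptors, hypoxia-inducible factor targets, and hepatocytes. These were tested with Fisher's exact test on called genes, adjusted over 49 tests. The naming rule takes Acadl and Acadvl, and per comparison the 8 rising and 8 falling genes with the largest log2 change among called genes with a mean of at least 1 CPM, a symbol other than a predicted gene, and no overlap between the libraries of the sides. It adds up to 4 called members of each fixed list, or up to 2 of the most abundant where none was called. The rule takes more genes than the text names: 56 of 127 are named for the labelled Acadl KO against wild type, 46 of 145 against Acadl Het, 47 of 116 for Acadvl KO and 36 of 89 for the labelled Acadl KO against Acadvl KO. Which list members are named was decided after their values were seen, and 2 members that had been named are not reported here. Genes outside the rule (Atf4, Nop58, Rrs1, Ctla4, Vegfa, Ankrd37, Xaf1, Adra1a, Asns in Acadl Het, Junb, Alb, Nppa, Mir324 and those called in opposite directions) were chosen after their values were seen.

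Library pairs of 1 genotype differed by 15.7 to 557.7 in chi-square per degree of freedom, so none was counted as a copy of another. The gene tests and camera with the preset correlation were tested on simulated counts drawn from the real means. For the gene tests 200 genes were changed by known folds. Of genes changed 2-fold, 76.1% were recovered among 15707 genes for the labelled Acadl KO against wild type, 83.6% among 15683 against Acadl Het, 79.1% among 15714 for Acadl Het against wild type and 85.1% among 15642 for Acadvl Het. The share was 76.1% among 15700 for Acadvl KO, 79.1% among 15727 for the labelled Acadl KO against Acadvl KO and 49.3% among 15661 for the interaction. False calls ran from 4 of 176 calls for Acadvl Het to 16 of 169 for Acadl Het against wild type. They were 15 of 167 for the labelled Acadl KO against Acadvl KO. A list raised 1.3-fold was called by camera and 0 of 29 lists sharing no member with it were. Genes were drawn independently of each other, so this could not show whether correlation between genes leads to false list calls.

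Alternatives were size factors by the median of ratios, no filter on low counts, DESeq2 1.42.0, limma voom, edgeR with legacy dispersions, no batch term, each batch alone, only the genotypes compared, other control genotypes, the first title number as a random effect, and each of the 24 libraries left out. Alternatives without Rn45s and without libraries above 10 CPM of Alb were chosen after seeing the data. Overlap of the effects of the KO labels was set beside 20 simulations of unchanged groups against the same controls. Single values were compared with exact permutation tests, or with 100000 resamples where samples were many.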

Results

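Messenger RNA was measured in 24 heart samples of male mice aged 14 weeks, 1 library each. Acadl encodes long-chain acyl-CoA dehydrogenase and Acadvl encodes very long-chain acyl-CoA dehydrogenase, enzymes that take the opening step of fatty acid oxidation in mitochondria. The 6 genotypes were Acadl wt / Acadvl wt (wild type, n = 4), Acadl Het / Acadvl wt (n = 4), Acadl Het / Acadvl Het (n = 3), Acadl Het / Acadvl KO (n = 4), Acadl KO / Acadvl wt (n = 4) and Acadl KO / Acadvl Het (n = 5). Total counts ran from 34320838 to 51743114 per library, and 17571 to 18351 genes had at least 1 count. RNA was isolated in 2 batches of 9 and 15 libraries, and every genotype had libraries in both. All pairs of libraries of 1 genotype differed by more than sampling noise. Rn45s, the ribosomal RNA precursor, took 17.258% of the counts of Acadl Het / Acadvl Het replicate 1, against 0.558% in the next library.

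The targeted genes were compared first, since they check the labels. Acadvl (chromosome 11, 70010183 to 70015428, mm10) followed its labels within each Acadl label: it stood at 1632 ± 82.5 CPM in Acadl Het / Acadvl wt hearts (SD, n = 4), 1079 ± 41.9 CPM in Acadl Het / Acadvl Het hearts (n = 3) and 599.2 ± 121 CPM in Acadl Het / Acadvl KO hearts (n = 4). It was 2115 ± 258 CPM in Acadl KO / Acadvl wt hearts (n = 4) and 1430 ± 178 CPM in Acadl KO / Acadvl Het hearts (n = 5), and the latter, at 1163 to 1645 CPM, overlapped wild type at 1550 to 1593 CPM.
Acadl (chromosome 1, 66830839 to 66863309, mm10) went against its labels. It was 1358 ± 42 CPM in wild type (n = 4) and 1894 ± 167 CPM in Acadl KO / Acadvl wt hearts (n = 4), a log2 rise of 0.47 (SE 0.07, edgeR adjusted p = 1.818e-05). The lowest of the 9 libraries labelled Acadl KO held 1697 CPM and the highest of the 15 others 1625 CPM. These counts cover the whole gene and do not show which exons the reads came from. Every direction given for Acadl KO therefore rests on the label and not on Acadl reads, and these libraries are called labelled Acadl KO. Acadl Het likewise rests on the label and not on Acadl reads, since Acadl was 1549 ± 99.8 CPM in Acadl Het / Acadvl wt hearts (n = 4), not below wild type.

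**Figure D1:**
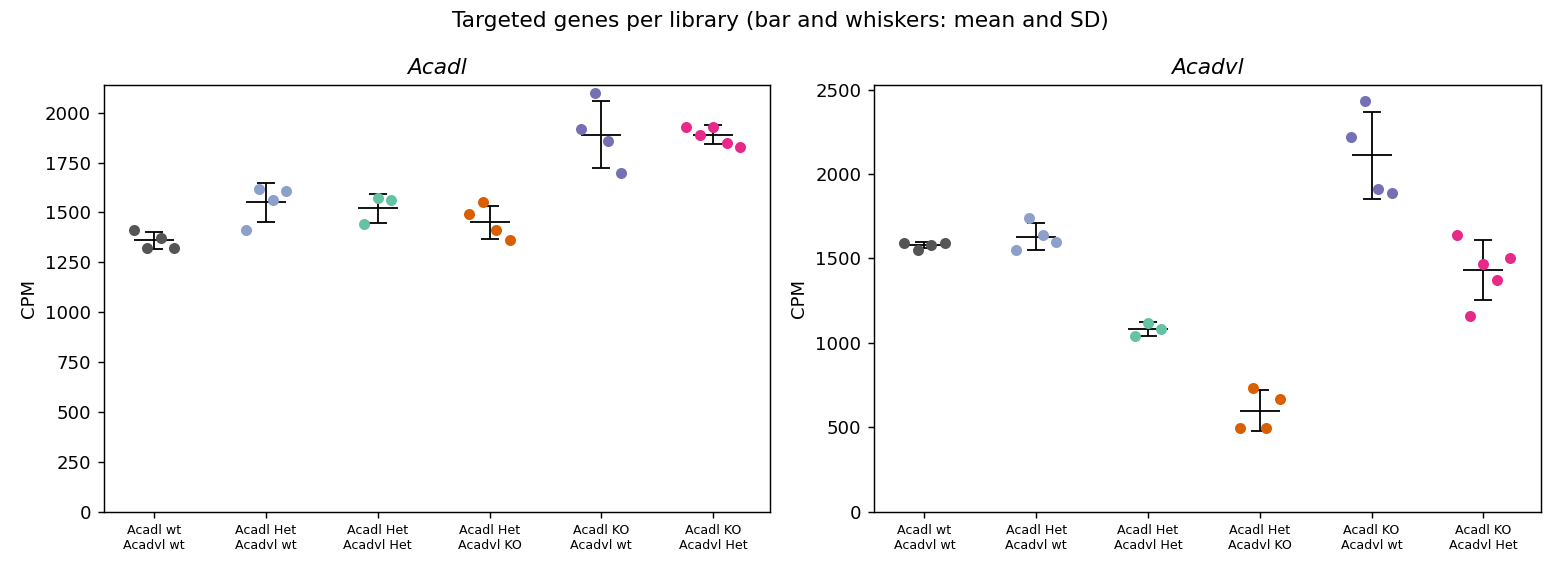
Acadl (left) and Acadvl (right) in CPM for each library, by genotype, with the mean and SD of each genotype as a bar with whiskers. Acadvl had its lowest mean, 599.2 CPM, in Acadl Het / Acadvl KO hearts, while Acadl had its highest means, 1894 and 1887 CPM, in the libraries labelled Acadl KO.

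The comparison of libraries labelled Acadl KO (Acadvl wt) with wild type asked what the loss of long-chain acyl-CoA dehydrogenase changed in the heart. Genes of the integrated stress response were among those that rose the most. Gdf15, a secreted stress cytokine, rose from 1.72 ± 0.248 to 31.4 ± 17.2 CPM (SD, n = 4 each), a log2 change of 4.18 (SE 0.63, edgeR adjusted p = 5.613e-05). Asns, which makes asparagine, rose by a log2 of 3.83 (SE 0.44, edgeR adjusted p = 3.521e-06), and Trib3, a pseudokinase induced by ATF4, by 3.46 (SE 0.55). Fgf21, a secreted metabolic hormone, had 2 to 4 counts in each wild-type library and 26 to 325 in each library labelled Acadl KO, and Vmn2r3 had 0 to 2 against 4 to 45. Lrrc10b (3.56), Grin2c (3.19) and Atf3 (3.08) completed the 8 rises on the log2 scale that the naming rule takes. The 8 falls it takes were in Aqp4, a water channel, at -4.59 (SE 0.32, edgeR adjusted p = 7.132e-09), B3galt2 at -3.93, Gal3st3 at -3.14 and Myl1, a myosin light chain, at -2.93. They include Smim5 (-2.91), Phkg1, the catalytic subunit of muscle phosphorylase kinase (-2.86, SE 0.18), Itgb6 (-2.83) and Sec14l5 (-2.80).

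Counts per fixed list are over all genes tested, and the count adjusted over the list alone is given where it differed. Of all genes tested, 19.6% rose and 17.6% fell against wild type, and 26.7% and 27.9% against Acadl Het. The shares were 12.9% and 11.5% for Acadvl KO, and 1.77% and 2.66% for the labelled Acadl KO against Acadvl KO. Lists with counts near these shares did not stand out from other genes. Of the ATF4 and integrated stress response targets 23 of 32 rose and 1 fell (27 and 1 adjusted over the list alone). Of the cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 18 of 22 rose and 0 fell, among them Aars at 1.41 (SE 0.12), Yars (1.38), Cars (1.26) and Iars (1.15). Of the amino acid transporters 8 of 21 rose and 1 fell (11 and 2 adjusted over the list alone), and Slc7a5 (2.34) and its partner Slc3a2 (1.60) were among those that rose. Of the serine and one-carbon genes 7 of 16 rose and 3 fell (8 and 3 adjusted over the list alone), with Mthfd2 at 2.78 (SE 0.40), Shmt1 at 1.24 and Psat1 at 1.13, though Psat1 was at -0.24 within batch 1. Of the NRF2 targets, which defend against oxidants, 15 of 20 rose and 0 fell (16 and 0 adjusted over the list alone), including Hmox1 (2.60), Srxn1 (2.41), Gsta1 (2.22) and Osgin1 (2.02). Of the PPAR-alpha targets 16 of 24 rose and 0 fell, including the peroxisomal enzyme Ehhadh (1.79) and the thioesterase Acot1 (1.64). limma's camera on voom log2 CPM called the ATF4 (adjusted p = 1.46e-08), synthetase (2.24e-09), transporter (0.0108), NRF2 (2.17e-08) and PPAR-alpha (3.6e-08) lists but not the serine list (0.206). None of these camera calls held with an estimated correlation. The camera adjusted p was then 0.338 for the ATF4, synthetase and transporter lists and 0.0866 for the NRF2 and PPAR-alpha lists. Fry called all of these lists (fry adjusted p from 1.58e-07 to 0.000186), and the serine list too (fry adjusted p = 0.00566).

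Of the mitochondrial fatty acid oxidation genes 9 of 23 rose and 2 fell. Cpt1b (0.66) and Slc25a20 (0.64), which carry acyl groups into mitochondria, were among those that rose and Acad12 (-0.61) among those that fell. Of the glycolysis genes 12 of 22 rose and 3 fell (13 and 3 adjusted over the list alone), and isoforms of a regulatory enzyme moved apart, with Pfkfb2 at 1.53, Pfkfb1 at -1.25 and Pfkfb3 at -0.97. Of the pyruvate dehydrogenase control genes 7 of 14 rose and 3 fell, with Pdk4 at 0.95, Pdhb at 0.60 and Pdk1 at -0.58. Of the peroxisomal oxidation genes 8 of 18 rose and 2 fell (8 and 3 adjusted over the list alone). Of the oxidative phosphorylation genes encoded in the nucleus 2 of 30 rose and 1 fell (2 and 0 adjusted over the list alone). Of the branched-chain amino acid breakdown genes 2 of 22 rose and 5 fell. Camera called none of these 6 lists. Of the mitochondrial chaperones and proteases 8 of 14 rose and 0 fell (Afg3l2 (0.83), Hspe1 (0.76)), which camera called (adjusted p = 0.00733, and adjusted p = 0.543 with an estimated correlation). FOXO and atrophy genes were called too (adjusted p = 0.0133, and adjusted p = 0.72 with an estimated correlation): 6 of 12 rose and 0 fell (8 and 0 adjusted over the list alone), with Irs2 at 2.24 and Cdkn1a at 1.51. Of the interferon response genes 0 of 16 rose and 6 fell (0 and 7 adjusted over the list alone), with Ifit2 at -1.12 and Ifit3 at -1.06 (adjusted p = 0.00313, and adjusted p = 0.72 with an estimated correlation).

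Among the remaining lists, camera called the immediate early genes, of which 5 of 15 rose and 0 fell (adjusted p = 0.72 with an estimated correlation), and the nerve and Schwann cell markers, of which 0 of 10 rose and 4 fell (adjusted p = 0.681 with an estimated correlation). Camera called none of the lists that follow. Fry called some of them, including the skeletal muscle (fry adjusted p = 3.87e-05), atrial (0.00834) and cardiac stress (0.00566) lists, each downward. Of the atrial cardiomyocyte markers 0 of 10 rose and 4 fell, with Kcnj3 at -1.5, of the skeletal muscle markers 0 of 9 rose and 2 fell. Of the ventricular cardiomyocyte markers 2 of 12 rose and 2 fell, and of the cardiac stress and fetal genes 0 of 16 rose and 4 fell (0 and 3 adjusted over the list alone). Of the mitochondrial synthetases 6 of 17 rose and 1 fell (7 and 2 adjusted over the list alone), of the endoplasmic reticulum response genes 2 of 20 rose and 5 fell, with Herpud1 at 1.44 and Pdia4 at -0.70. Of the cholesterol synthesis genes 2 of 20 rose and 5 fell. Of the autophagy genes 6 of 20 rose and 3 fell, with Fnip1 at 1.09 and Sqstm1 at 0.80. Of the circadian output genes 3 of 16 rose and 3 fell, with Hlf at -1.49 and Dbp at -1.31. Of the adipocyte markers 2 of 9 rose and 0 fell, with Fabp4 at 1.11. Of the matrix and fibrosis genes 2 of 20 rose and 2 fell (1 and 2 adjusted over the list alone), of the fibroblast markers 1 of 12 rose and 0 fell (0 and 0 adjusted over the list alone). Of the endothelial markers 1 of 12 rose and 0 fell, and of the smooth muscle and pericyte markers 0 of 12 rose and 3 fell. Of the cell division genes 0 of 12 rose and 1 fell and of the erythroid markers 0 of 7 rose and 1 fell (2 and 1 adjusted over the list alone). edgeR called 0 of 14 macrophage and leukocyte markers, 0 of 9 lymphocyte markers and 0 of 9 epicardial markers at an adjusted p under 0.05. None of the mitochondrially encoded genes was measured.

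In all, edgeR called 5874 of 15804 genes, 3095 higher and 2779 lower, and Acadvl was 0.42 higher (SE 0.12, edgeR adjusted p = 0.007564). The count was 4511 within batch 2 and 86 within batch 1, where 1 library labelled Acadl KO stood against 2 of wild type. It was 3871 without the libraries above 10 CPM of the liver gene Alb, which include replicates 2 and 3 of the libraries labelled Acadl KO. Of the 121 called genes that the naming rule takes, 30 lost their call when some 1 library was left out, but only 1 of the 56 named. That was Dbp, whose call was lost without any 1 of Acadl KO / Acadvl wt replicate 1 or 2 or wild-type replicate 4 (-1.23 to -0.66).

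**Figure D2:**
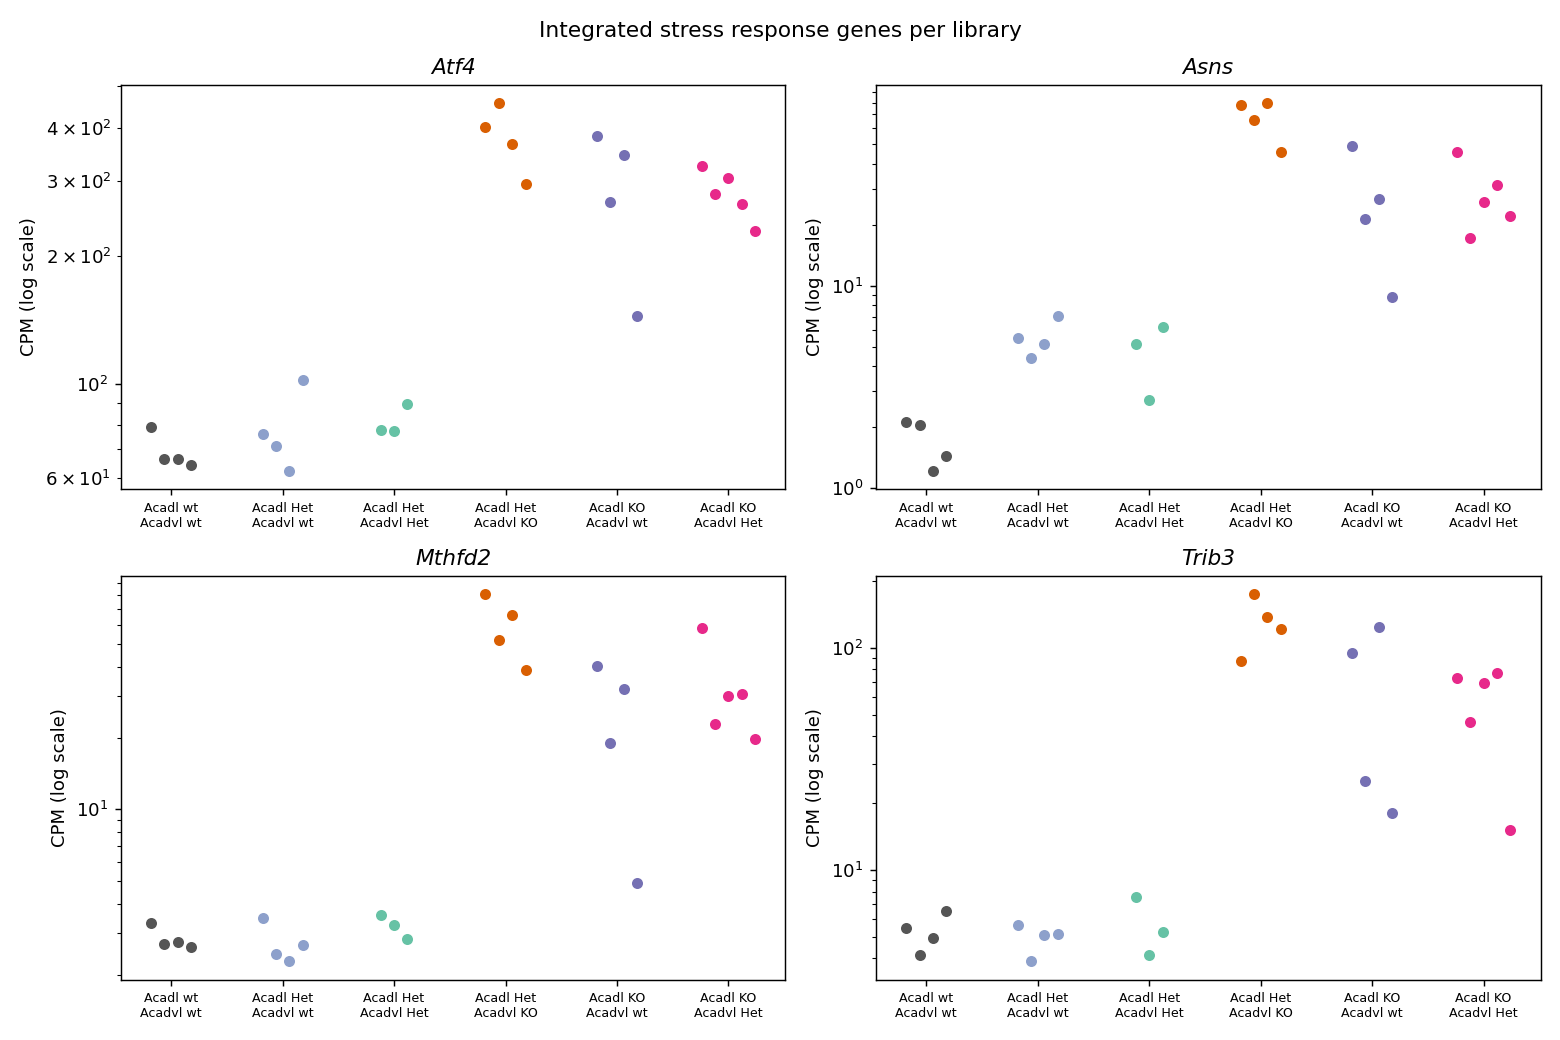
Atf4, Asns, Mthfd2 and Trib3 in CPM on a log axis, 1 point per library, by genotype. For each gene the libraries of the 3 genotypes with a KO label lie above those of the 3 others, and Acadl KO / Acadvl wt replicate 4 has the lowest Asns (8.74 CPM), Atf4 (144 CPM) and Mthfd2 (4.88 CPM) of the libraries with a KO label.

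The 9 libraries labelled Acadl KO were also compared with the 7 Acadl Het libraries that carry no KO, balanced over Acadvl wt and Acadvl Het. On the log2 scale Gdf15 rose by 3.88 (SE 0.46, edgeR adjusted p = 1.382e-06), Trib3 by 3.44, Mthfd2 by 3.10 (SE 0.30), Lrrc10b by 3.53, Grin2c by 3.03 and Kcnc1, a potassium channel, by 2.75. Fgf21 had 26 to 325 counts per library in the 9 against 1 to 13 in the 7, and Vmn2r3 had 4 to 148 against 0 to 5. Aqp4 fell by 5.24 on the log2 scale (SE 0.24, edgeR adjusted p = 1.941e-12), Phkg1 was at -3.24 (SE 0.13), B3galt2 at -3.85, Gal3st3 at -3.11, Pirt at -3.15 and Ankrd37 at -3.05. The chemokines Ccl7 (-4.39) and Ccl2 (-4.05) fell too. Ccl2 was 9.89 ± 4.82 CPM in Acadl Het / Acadvl wt hearts, 1.99 ± 1.05 CPM in wild type and 0.744 ± 0.587 CPM in the libraries labelled Acadl KO with Acadvl wt (SD, n = 4 each).

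Of the ATF4 targets 28 of 32 rose and 1 fell (29 and 1 adjusted over the list alone), of the cytosolic synthetases 18 of 22 rose and 1 fell (18 and 2 adjusted over the list alone) (Aars (1.41), Cars (1.32), Yars (1.26)). Of the NRF2 targets 16 of 20 rose and 0 fell (Gsta1 (2.56), Srxn1 (2.04)) and of the PPAR-alpha targets 17 of 24 rose and 1 fell (Plin5 (1.35), Ehhadh (1.32)). Camera called these lists (adjusted p from 1.15e-08 to 5.12e-05), but adjusted p = 0.538, 0.538, 0.183 and 0.41 with an estimated correlation. Fry called them as well (fry adjusted p from 8.68e-09 to 7.58e-06). Of the amino acid transporters 13 of 21 rose and 4 fell, with Slc7a5 at 2.47 (adjusted p = 0.538 with an estimated correlation). Of the interferon response genes 0 of 16 rose and 14 fell (0 and 15 adjusted over the list alone), with Stat2 at -0.86 and Oas1a at -0.79. Of the atrial markers 0 of 10 rose and 7 fell, with Sln at -2.08, Kcnj3 at -1.71 and Myl7 at -1.69 (adjusted p = 0.667 with an estimated correlation for both). Of the skeletal muscle markers 0 of 9 rose and 3 fell, and camera did not call them. Myl1 (-2.17), a skeletal muscle gene near Acadl, counts in both the atrial and the skeletal list. Of the endoplasmic reticulum response genes 2 of 20 rose and 11 fell, with Pdia4 at -1. Of the fatty acid oxidation genes 9 of 23 rose and 4 fell, with Cpt1b at 0.55 and Acad12 at -0.68, and camera called neither list. Of the cardiac stress genes 1 of 16 rose and 5 fell, with Ctgf at -1.65 and Ankrd1 at -1.32, and of the matrix genes 2 of 20 rose and 7 fell (2 and 4 adjusted over the list alone), with Timp1 at -2.19. Of the fibroblast markers 1 of 12 rose and 6 fell (2 and 8 adjusted over the list alone), with Lum at -0.73 and Tcf21 at -0.66, and of the leukocyte markers 2 of 14 rose and 4 fell, with Cx3cr1 at -1.73 and Ccr2 at -1.55. Of the circadian output genes 8 of 16 rose and 3 fell, with Hlf at -1.43 and Ciart at 1.67, and camera called none of these 5 lists. Of the glycolysis genes 14 of 22 rose and 3 fell, with Ldha at -0.69 (camera adjusted p = 0.0341, and adjusted p = 0.694 with an estimated correlation). Acadl was 0.30 higher (SE 0.05) and Acadvl 0.39 higher (SE 0.08).

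edgeR called 8639 genes, 4225 higher and 4414 lower, and camera called 10 lists, with 0 called with an estimated correlation. The count of genes was 7102 within batch 2 and 2112 within batch 1. It was 6380 without the libraries above 10 CPM of Alb, with Acadl Het / Acadvl wt as the controls. All 3 Acadl Het / Acadvl Het controls held liver transcripts (Alb 19.8 to 159 CPM), and of 30 hepatocyte genes, a list written after these values were seen, 20 fell and 0 rose (median log2 change -2.42). Lars2, a mitochondrial synthetase at -2.20, rested on Acadl Het / Acadvl Het replicate 1, the library rich in Rn45s (-0.17 without it), and was at -2.63 within batch 2 and 0.08 within batch 1. Of the 145 called genes that the naming rule takes, 18 lost their call when some 1 library was left out, and 3 of the 46 named, Lars2, Lum and Myl7. Lum was not called without Acadl Het / Acadvl Het replicate 2 (-0.54). Myl7 was not called without any 1 of Acadl Het / Acadvl Het replicate 2, Acadl Het / Acadvl wt replicate 3, Acadl KO / Acadvl wt replicates 3 and 4 or Acadl KO / Acadvl Het replicates 4 and 5 (-1.67 to -1.33).

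**Figure D3:**
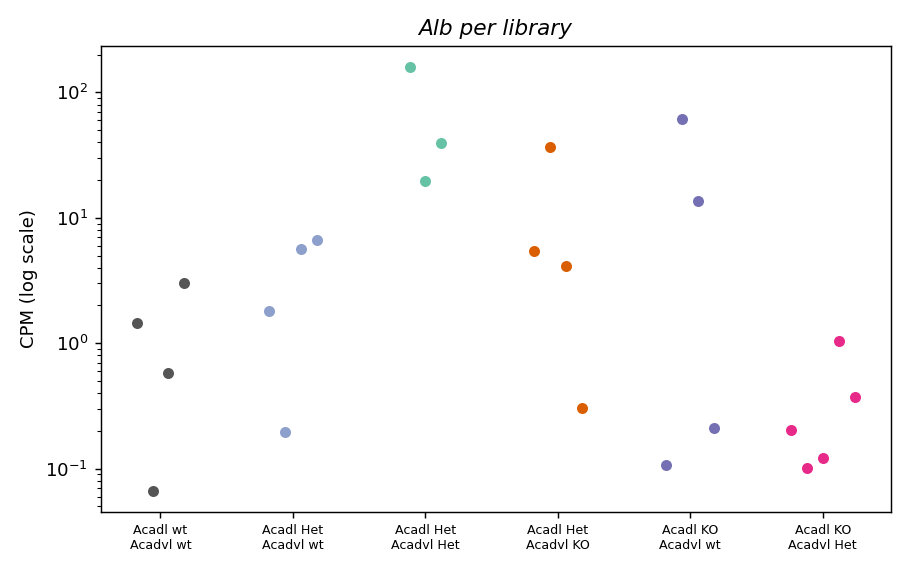
Alb, a liver gene, in CPM on a log axis, 1 point per library, by genotype. The 3 Acadl Het / Acadvl Het libraries lie between 19.8 and 159 CPM, and the libraries of the Acadl KO / Acadvl Het genotype at 1.04 CPM or less.

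Acadl Het / Acadvl wt hearts were compared with wild type to see whether expression differed with the Acadl Het label. Acadl was 0.19 higher (SE 0.06, edgeR adjusted p = 0.9272) and Acadvl 0.05 higher (SE 0.12), and neither difference was called. Among the most abundant members of the fixed lists, Hadha, a subunit of the trifunctional protein, differed by 0.08 (SE 0.08), Vldlr by 0.09 (SE 0.11), Aars by 0.03 (SE 0.12) and the immediate early gene Btg2 by 0.93 (SE 0.31). edgeR called 0 genes, limma voom 0 and DESeq2 1, and 541 genes had an unadjusted p under 0.05. The gene called by DESeq2 was Junb, an immediate early gene named after its values were seen, at 1.37 in edgeR (SE 0.27, edgeR adjusted p = 0.4861), which edgeR called without Acadl Het / Acadvl Het replicate 3. Of the 15 immediate early genes 6 were called adjusted over the list alone (median 0.92, camera adjusted p = 8.79e-13, and adjusted p = 0.243 with an estimated correlation). Camera called 12 of the lists, with 0 called with an estimated correlation and 0 by fry. Aars was at -0.17 within batch 1, and leaving out wild-type replicate 1 or 2 or Acadl Het / Acadvl wt replicate 2 or 4 gave -0.05, -0.03, 0 and -0.02. edgeR called 0 genes within batch 2 and 0 within batch 1.

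Acadvl Het was compared with Acadvl wt over both the Acadl Het and the labelled Acadl KO hearts, 8 libraries on each side. Acadvl fell by 0.58 on the log2 scale (SE 0.08, edgeR adjusted p = 0.005331). Xaf1, an interferon-induced gene on the same chromosome (72301629 to 72313733), rose by 1.16 (SE 0.15, edgeR adjusted p = 0.001512). It is named after its values were seen. It was 17.2 ± 1.65 CPM in Acadl Het / Acadvl Het hearts (SD, n = 3) and 6.75 ± 1.5 CPM in Acadl Het / Acadvl wt hearts (n = 4), and 8.39 ± 1.65 against 4.36 ± 1.24 CPM in the labelled Acadl KO hearts (n = 5 and 4). These were the 2 genes edgeR called, against 9 by DESeq2 and 2 by limma voom, and 697 genes had an unadjusted p under 0.05. Within batch 2 and within batch 1 edgeR called 0 genes, with Xaf1 at 1.23 and 0.93. Genes not called were Acadl at -0.02 (SE 0.05), Aars at 0.01 (SE 0.08), Vldlr at -0.13 (SE 0.08) and Lars2 at 2.05 (SE 0.55), and the sign of each but Vldlr turned within a batch or without a library. The value of Lars2 rested on Acadl Het / Acadvl Het replicate 1, with 19600 CPM against 414 and 351 CPM in the other libraries of that genotype, and was 0.03 without it. Of the 12 cell division genes 2 were called adjusted over the list alone (median 0.49, camera adjusted p = 4.27e-09, and adjusted p = 0.846 with an estimated correlation). Camera called 10 lists in all, with 0 called with an estimated correlation and 0 by fry. The count of lists was 6 without Acadl KO / Acadvl wt replicate 1 or Acadl KO / Acadvl Het replicate 3 and 5 without Acadl KO / Acadvl wt replicate 3 or Acadl Het / Acadvl wt replicate 4.

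Acadvl KO was compared with Acadvl wt on the Acadl Het background, to show the loss of very long-chain acyl-CoA dehydrogenase. Acadvl fell by 1.45 on the log2 scale (SE 0.12, edgeR adjusted p = 9.689e-08), and Acadl, not called, differed by -0.10 (SE 0.07, edgeR adjusted p = 0.261). On the same scale Trib3 rose by 4.61 (SE 0.56), Gdf15 by 4.61 (SE 0.62, edgeR adjusted p = 4.006e-05), Mthfd2, a mitochondrial one-carbon enzyme, by 4.24 (SE 0.41), Asns by 3.46 (SE 0.40), Slc7a5 by 3.17 and Sesn2 by 3.14. Fgf21 had 71 to 584 counts per library against 2 to 7, and Vmn2r3 55 to 358 against 0 to 2. Aqp4 fell by 4.66 (SE 0.31, edgeR adjusted p = 7.719e-09), Cacng6, a calcium channel subunit, was at -3.14, B3galt2 at -2.96, Tmem100 at -2.89, Ptx3 at -2.58, Wif1 at -2.55, Phkg1 at -2.45 and Angpt1 at -2.32.

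Of the ATF4 targets 29 of 32 rose and 0 fell (29 and 1 adjusted over the list alone), of the cytosolic synthetases 15 of 22 rose and 0 fell (Cars (1.5), Aars (1.44), Yars (1.43), Gars (1.35)). Of the amino acid transporters 11 of 21 rose and 0 fell (11 and 1 adjusted over the list alone) (Slc7a3 (3.07), Slc1a4 (2.89)) and of the serine and one-carbon genes 8 of 16 rose and 2 fell (10 and 4 adjusted over the list alone) (Psat1 (2.58), Phgdh (2.34)). Camera called all 4 lists (adjusted p from 2.26e-20 to 0.00381), but adjusted p = 0.0874, 0.245, 0.0627 and 0.194 with an estimated correlation. Of the fatty acid oxidation genes 2 of 23 rose and 11 fell (2 and 13 adjusted over the list alone), with Acad12 at -0.75, Acad10 at -0.57 and Cpt2 at -0.51 (camera adjusted p = 0.000148, and adjusted p = 0.759 with an estimated correlation). Of the branched-chain amino acid breakdown genes 0 of 22 rose and 13 fell (0 and 14 adjusted over the list alone), with Ppm1k at -0.72, Mccc2 at -0.50 and Acadsb at -0.48 (camera adjusted p = 4.05e-06, and adjusted p = 0.46 with an estimated correlation). Of the oxidative phosphorylation genes encoded in the nucleus 0 of 30 rose and 9 fell (0 and 16 adjusted over the list alone), with Sdhc at -0.44, Cox6c at -0.32 and Sdha at -0.31 (camera adjusted p = 5.54e-05, and adjusted p = 0.759 with an estimated correlation). Of the NRF2 targets 8 of 20 rose and 1 fell (13 and 1 adjusted over the list alone), with Srxn1 at 2.17 and Osgin1 at 1.96 (adjusted p = 0.208 with an estimated correlation). Of the PPAR-alpha targets 10 of 24 rose and 1 fell, with Ehhadh at 1.15 (adjusted p = 0.759 with an estimated correlation). Of the cardiac stress genes 2 of 16 rose and 3 fell (2 and 5 adjusted over the list alone), with Acta1 at 1.66, Nppb at 1.06 and Kcnd2 at -1.5. Of the leukocyte markers 2 of 14 rose and 0 fell (1 and 0 adjusted over the list alone), with Cd68 at a log2 of 1, and of the fibroblast markers 2 of 12 rose and 0 fell, with Dpep1 at 0.89. Of the atrial markers 0 of 10 rose and 2 fell, with Kcnj3 at -1.75, and of the pyruvate dehydrogenase control genes 2 of 14 rose and 5 fell (3 and 5 adjusted over the list alone), with Pdk1 at -0.81. Camera called none of these 5 lists. Of the glycolysis genes 10 of 22 rose and 2 fell (14 and 2 adjusted over the list alone), with Pfkfb2 at 1.06 and Pfkfb1 at -1.68 (camera adjusted p = 0.0241, and adjusted p = 0.759 with an estimated correlation).

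edgeR called 3853 genes, 2031 higher and 1822 lower, and camera called 11 lists, with 0 called with an estimated correlation. The count was 2631 within batch 2, 208 within batch 1, where 1 Acadl Het / Acadvl KO library stood against 2 controls, and 1984 with only the libraries of these genotypes in the fit. Of the 111 called genes that the naming rule takes, 25 lost their call when some 1 library was left out, but only 1 of the 46 of them named. That was Nppb, not called without any 1 of Acadl Het / Acadvl wt replicates 1, 2 and 3 or Acadl Het / Acadvl KO replicates 1 and 2 (0.95 to 1.15).

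**Figure D4:**
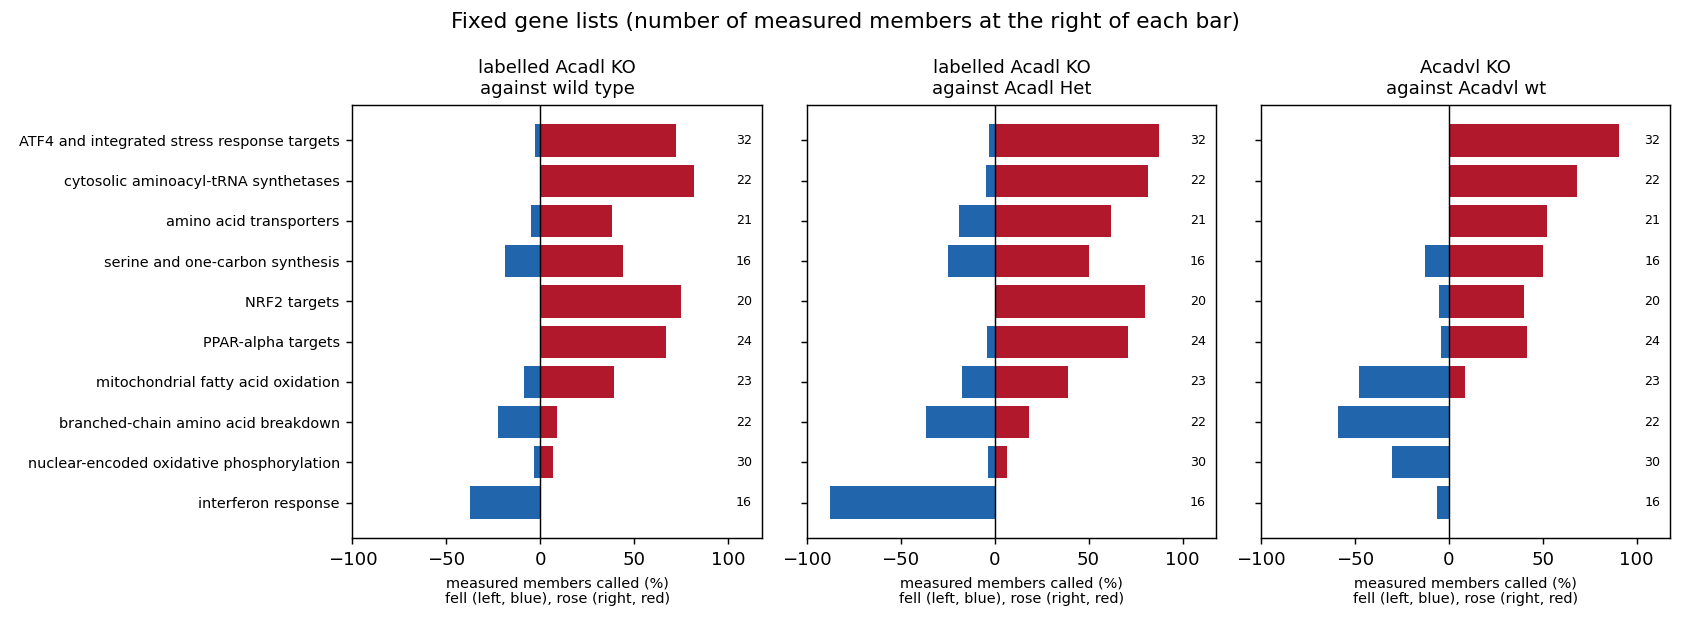
Share of the measured members of 10 fixed gene lists that rose (right, red) or fell (left, blue), in percent, in 3 comparisons, with the number measured at the right of each bar. ATF4 targets rose in 23, 28 and 29 of 32, and fatty acid oxidation genes fell in 2, 4 and 11 of 23.

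The libraries labelled Acadl KO (Acadvl wt) were then set directly against Acadl Het / Acadvl KO. This asked how hearts labelled as lacking each enzyme differ. The Acadvl KO hearts also carry the Acadl Het label, and no Acadl wt / Acadvl KO hearts were sampled. An effect of that Acadl label can therefore not be separated here. On the log2 scale Acadvl was 1.82 higher (SE 0.12, edgeR adjusted p = 9.079e-09) and Acadl 0.38 higher (SE 0.06) in the labelled Acadl KO. Tmem100 (2.55), Rbp7 (1.98), Gsta1 (1.77), Slfn8 (1.75), Rsad1 (1.35), Adora2a (1.32) and Tmem52 (1.21) were higher. Adam8 (-2.84), the matrix protein Tnc (-2.74), Myl1 (-2.63), Timp1 (-2.62), Xaf1 (-2.29), Ltbp2 (-1.89) and Wisp1 (-1.77) were lower, and Vmn2r3 had 4 to 45 counts per library against 55 to 358. Of the ATF4 targets 0 of 32 were higher and 8 were lower (1 and 10 adjusted over the list alone), with Phgdh at -1.54, Mthfd2 at -1.39, Asns at -1.38 and Psat1 at -1.33 (adjusted p = 0.147 with an estimated correlation). Of the amino acid transporters 0 of 21 were higher and 5 were lower (1 and 6 adjusted over the list alone), with Slc7a11 at -1.09 (adjusted p = 0.13 with an estimated correlation). Of the fatty acid oxidation genes 9 of 23 were higher and 0 were lower (18 and 0 adjusted over the list alone), with Acaa2 at 0.38 and Cpt2 at 0.36 (adjusted p = 0.138 with an estimated correlation). Of the PPAR-alpha targets 8 of 24 were higher and 0 were lower (11 and 1 adjusted over the list alone), with Acot1 at 0.96, Ehhadh at 0.68 and Mlycd at 0.48 (adjusted p = 0.13 with an estimated correlation). Of the NRF2 targets 3 of 20 were higher and 1 was lower (7 and 1 adjusted over the list alone), with Nqo1 at 0.79 and Gsta4 at 0.74 (adjusted p = 0.177 with an estimated correlation).

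Of the branched-chain amino acid breakdown genes 3 of 22 were higher and 0 were lower (15 and 0 adjusted over the list alone), with Bckdhb at 0.31 and Pccb at 0.26 (adjusted p = 0.164 with an estimated correlation). Of the matrix genes 0 of 20 were higher and 5 were lower (0 and 9 adjusted over the list alone), with Fn1 at -0.59 (adjusted p = 0.224 with an estimated correlation). Of the leukocyte markers 0 of 14 were higher and 5 were lower (1 and 12 adjusted over the list alone), with Itgam at -1.32, C1qa at -0.64 and C1qb at -0.61 (adjusted p = 0.197 with an estimated correlation). Of the cytosolic synthetases 0 of 22 were higher and 1 was lower, Gars (-0.49) being the 1 called, and camera did not call the list. Camera called 18 lists in all, and with an estimated correlation it called 0.

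edgeR called 700 genes, 280 higher and 420 lower, and the count rested on few libraries. It was 217 and 131 without Acadl KO / Acadvl wt replicates 1 and 2, and 248 and 278 without Acadl Het / Acadvl KO replicates 3 and 4. It was 54 within batch 2, 5 within batch 1, 77 without the libraries above 10 CPM of Alb, 46 with only these genotypes in the fit and 1214 by DESeq2. With Acadl KO / Acadvl Het in place of Acadl KO / Acadvl wt it was 1386. Of the 58 called genes that the naming rule takes, 40 lost their call when some 1 library of the 24 was left out, and so did 19 of the 36 genes named here. Without Acadl KO / Acadvl wt replicate 2 the calls of Rbp7, Adora2a, Tmem52, Tnc, Timp1, Ltbp2, Wisp1, Mthfd2, Asns, Psat1, Bckdhb, Pccb, Gars, Itgam, C1qa, C1qb, Acaa2, Cpt2 and Ehhadh were all lost. Over the libraries whose removal ended a call, Asns was -1.49 to -1.10, Mthfd2 -1.42 to -1.28, Psat1 -1.19 to -1.16, Timp1 -2.72 to -1.46, Tnc -2.74 to -1.91, Rbp7 1.16 to 2.09, Itgam -1.42 to -1.28, Ehhadh 0.56 to 0.60 and Acaa2 0.31 to 0.39. Cpt2 was lost without any 1 of 17 libraries, Wisp1 of 14, Acaa2 of 11 and Gars of 9, controls of other comparisons included.

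The interaction asked whether the loss of 1 Acadvl allele acts otherwise in libraries labelled Acadl KO than in Acadl Het hearts. The term was 0.04 for Acadl (SE 0.09) and 0.03 for Acadvl (SE 0.17, edgeR adjusted p = 0.997). edgeR called 0 genes, limma voom 0 and DESeq2 100, and 817 genes had an unadjusted p under 0.05. edgeR called 45 genes without the batch term, 0 within batch 2 and 0 within batch 1. The term was negative for 96 of the 100 genes called by DESeq2 and for all 45 called without the batch term. Whether liver transcripts account for this was not tested. Leaving out 1 library gave 92 genes without Acadl Het / Acadvl Het replicate 2, 62 without Acadl Het / Acadvl KO replicate 2 and 58 without Acadl KO / Acadvl wt replicate 1. It gave 39 without Acadl KO / Acadvl wt replicate 4, 25 without Acadl Het / Acadvl KO replicate 4 and 12 without Acadl Het / Acadvl wt replicate 4. Of the epicardial and mesothelial markers 0 of 9 were called by edgeR, with a median log2 term of -1.21 (camera adjusted p = 1.65e-05, and adjusted p = 0.782 with an estimated correlation). Of the 30 hepatocyte genes 0 were called by edgeR, with a median log2 term of -7.44, and all 3 Acadl Het / Acadvl Het libraries held liver transcripts. That list was written after those transcripts were seen. Camera called 5 of the fixed lists, with 0 called with an estimated correlation and 0 by fry. It called 10 without Acadl Het / Acadvl wt replicate 2 and 8 without any 1 of Acadl KO / Acadvl Het replicates 1 and 5, Acadl KO / Acadvl wt replicate 3, Acadl Het / Acadvl wt replicate 3 or Acadl Het / Acadvl Het replicate 3.

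The effects of the labelled Acadl KO and of Acadvl KO, each taken against the same 4 Acadl Het / Acadvl wt libraries, were compared across genes. Both called 1508 genes higher, among them Atf4, and 1307 lower, where independent lists of those sizes would share 368 and 304. Opposite calls were made for 7 genes, namely Acadvl, Mir324, Xaf1, Rsad1, Thbs3, Adam8 and Ccnd1, named here after their values were seen. Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.743 and Spearman's rho 0.718. In 20 simulations, unchanged groups set against the same controls gave a median r of 0.5165. At most 1 gene per direction was called in any of these groups. That they shared 0 called genes therefore does not show how far shared controls add to shared calls. The covariance was 0.242 against 0.0417 in the simulations, a difference of 0.201, and 0.1784 over genes with a mean of 1 CPM or more. With the controls split into 2 and 2, 612 to 936 genes were called higher by both and 491 to 673 lower over 6 splits, and r was 0.4043 to 0.6147. The covariance was then 0.1784 to 0.237. These splits share no control library, so the simulated r, from shared controls, is no measure for them.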

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

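The tests of Acadl in libraries labelled Acadl KO, of liver transcripts, and of the signs of genes near Acadl and Acadvl in hearts with a Het label were chosen only after the result was seen, and the criteria of the last were rewritten after it. The tests of the shares of called genes near Acadl and Acadvl and of other splits of the libraries were chosen before, though what the shares leave open was reworded after their values were seen, and those of 2-fold changes and of the make-up of splits were not.

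Of 100 groups tested for a library far from the others, 7 held one, where chance gives about 5 percent of groups. In the Acadl KO / Acadvl Het genotype, replicate 1 had 58.1 CPM of Mthfd2 against 19.8 to 30.5 in the other 4, and 4.28 CPM of Vmn2r3 against 0.521 to 1.16, while replicate 2 had 1920 CPM of Nppa, an atrial peptide, against 131 to 343. Wild-type replicate 1 had 79.1 CPM of Atf4 against 64.2 to 66.4 in the other 3. Acadl Het / Acadvl KO replicate 3 had 39.2 CPM of Myl1 against 21.6 to 22.1, and replicate 2 had 36.8 CPM of Alb against 0.304 to 5.41. Acadl KO / Acadvl wt replicate 1 had 1.63 CPM of Ccl2 against 0.429 to 0.474.

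Acadl reads were higher in the libraries labelled Acadl KO than in all others. Acadl labels mixed up between libraries would place some of the 9 within the range of the 15 others, and 0 of the 9 lay there, which argues against a swap of single libraries between these groups. An exchange of whole groups would leave no library in that range. Against Acadl Het / Acadvl wt, labelled Acadl KO and Acadvl KO shared 1508 genes called higher and 1307 called lower. Between Acadl Het / Acadvl wt and wild type 0 genes were called. These values argue against an exchange of labelled Acadl KO with wild type, but do not exclude it. The mean of Acadl was 1358 CPM in wild type, 1549 CPM in Acadl Het / Acadvl wt and 1894 CPM in Acadl KO / Acadvl wt. Reads from the disrupted allele may give this pattern, but 0 exons were counted separately in the files, so this cannot be told apart from a change of the intact transcript. A wrong label shared by all 9 libraries was not tested.

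Hepatocyte transcripts were high in 6 libraries: Alb stood at 159, 39.7 and 19.8 CPM in Acadl Het / Acadvl Het replicates 1, 3 and 2, at 61.7 and 13.6 CPM in Acadl KO / Acadvl wt replicates 2 and 3, and at 36.8 CPM in Acadl Het / Acadvl KO replicate 2. The median of the other hepatocyte genes followed Alb over the 24 libraries (Pearson's r 0.976 and Spearman's rho 0.97, each with a permutation p = 1e-05, the smallest that 100000 resamples can give; 1 relation computed). Pearson's r was 0.967 without the 2 libraries farthest from the median, 0.991 within batch 1 and 0.972 within batch 2, which is consistent with liver RNA in these libraries. Apoa1 reached 20.5 CPM and Mup3 20.5 CPM in Acadl Het / Acadvl Het. They reached 21.8 and 9.38 CPM in Acadl KO / Acadvl wt, and 13.2 and 6.2 CPM in Acadl Het / Acadvl KO. An effect of the Acadl Het / Acadvl Het genotype alone is argued against by 2 libraries of other genotypes with more Alb than the lowest of that genotype.

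Variants of the strain in which an allele was made can lie near it and change neighbouring genes, and the mice were of mixed background. Of genes within 10 Mb of Acadl, 51.6% were called for the labelled Acadl KO against Acadl Het, against 54.7% of all others (one-sided Fisher's exact p = 0.781). Near Acadvl 26.8% were called in Acadvl KO against 24.3% of all others (exact p = 0.171), while for changes of at least 2-fold the shares were 6.46% and 4.1% (exact p = 0.03). Without Mir324, which lies inside Acadvl and shares its reads, the shares were 6.17% and 4.1% (exact p = 0.0493), too close to the threshold to decide. The share of called genes near Acadvl was not below that elsewhere, and a p over 0.05 does not show that the shares were equal, so linked variants stay open there. Near Acadl the share of called genes was not above that elsewhere, and at least 2-fold changes were 3.23% near it against 7.68% (exact p = 0.988). With 54.7% of all others called, this test could not show a few linked genes, so linked variants stay open there too. Single genes may still be linked. The sign in hearts with a Het label matched for 59.8% of called genes near Acadvl against 51.6% elsewhere (exact p = 0.08). It matched for 60% near Acadl against 51.1% (exact p = 0.15). This leaves linkage open for genes such as Xaf1 and Myl1 (chromosome 1, 66924296 to 66945056). Myl1 was 31.8 ± 1.68 CPM in wild type, 22.7 ± 0.659 in Acadl Het / Acadvl wt and 20.4 ± 3.49 in Acadl Het / Acadvl Het. It was 4.22 ± 1.28 CPM in Acadl KO / Acadvl wt and 5.45 ± 1.24 in Acadl KO / Acadvl Het. In Acadl Het / Acadvl KO it was 26.1 ± 8.72 CPM. These values of Myl1 cannot tell a linked variant from an effect of Acadl itself.

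Other splits of the libraries were counted for each comparison. For the labelled Acadl KO against wild type 1 of 35 splits, the real one, called 5874 genes, and the highest other called 1. Against Acadl Het 1 of 100 splits called as many as 8639, the highest other calling 4288, and for Acadvl KO 1 of 35 called as many as 3853, the highest other calling 800. In these 3 comparisons only the real split reached its count, a share of 0.029, 0.01 and 0.029, the smallest these splits can give. Chance is thus an unlikely source of the count, but so few splits do not exclude it. The splits that called 4288 and 800 kept most libraries of the KO label on one side. For Acadvl Het 3 of 100 splits called at least the real 2 genes, a share of 0.03, but the highest other called 31. Why that split called so many times the real count was not tested, so the count alone does not show an effect of Acadvl Het. That split had 1 library above 10 CPM of Alb on one side and 4 on the other, and 2 and 4 libraries of batch 1. For the labelled Acadl KO against Acadvl KO 2 of 35 splits called at least 700 genes, the real one and 1 that called 1574, so chance cannot be excluded. The latter had both batch 1 libraries on one side, and edgeR called 54 genes within batch 2 and 5 within batch 1. What made that split call more genes was not tested. For Acadl Het against wild type the real count was 0, so all 35 of 35 splits reached it, the highest other calling 1, and for the interaction 100 of 100 reached 0, the highest other calling 26.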

How the results depend on the processing

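The alternatives without Rn45s and without libraries above 10 CPM of Alb were chosen after seeing the data, and all others were planned. No paired analysis was possible because the labels give no replicate numbers and do not say what the first title number, which some libraries share, stands for. That number was used as a random effect, with a consensus correlation of 0.0269. The deposited series table held the same counts, so the alternative of using it was not run. Without the libraries above 10 CPM of Alb, Acadl Het / Acadvl Het had no library left, so Acadvl Het and the interaction got no value, and the labelled Acadl KO was set against Acadl Het / Acadvl wt alone.

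Counts not given here stayed within 1.5 times of those reported. For the labelled Acadl KO against wild type the count was 86 within batch 1 and 3871 without the libraries above 10 CPM of Alb, and 4642 to 6070 leaving out 1 library. Against Acadl Het it was 2112 within batch 1 and 6380 without the libraries above 10 CPM of Alb, with Acadl Het / Acadvl wt as the controls, and 7848 to 8757 leaving out 1. For Acadl Het against wild type DESeq2 called 1, and leaving out 1 library gave 0 to 1. For Acadvl Het it was 0 within batch 2, 0 within batch 1 and 9 by DESeq2, and 2 to 3 leaving out 1. For Acadvl KO it was 208 within batch 1 and 1984 with only the genotypes compared, and 2774 to 3988 leaving out 1. For the labelled Acadl KO against Acadvl KO it was 54 within batch 2, 5 within batch 1, 46 with only the genotypes compared, 1386 with Acadl KO / Acadvl Het as the Acadl KO arm, 1214 by DESeq2 and 77 without the libraries above 10 CPM of Alb, and 131 to 999 leaving out 1. For the interaction it was 45 with no batch term and 100 by DESeq2, and 0 to 92 leaving out 1. Batches alone hold fewer libraries, with 1 library of some genotypes in batch 1, which was assumed to vary like the others. For the other settings the cause was not tested.

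Of the fixed lists, camera with an estimated correlation called 0 in each of the 7 comparisons. Fry called 18 for the labelled Acadl KO against wild type, 23 against Acadl Het, 0 for Acadl Het, 0 for Acadvl Het and 0 for the interaction. Batch 2 alone gave 5 lists for Acadvl Het and 9 for the interaction, and no batch term gave 9 for the interaction. Leaving out 1 library gave 8 to 13, 9 to 11, 10 to 13, 5 to 10, 9 to 13, 17 to 22 and 4 to 10 lists in the 7 comparisons in the order above. In the overlap of the effects of the KO labels, splitting the controls gave a median r of 0.5366, 831.5 genes higher in both and 639.5 lower, and genes with a mean of 1 CPM or more gave a covariance of 0.1784. The smaller counts go with fewer controls per side.

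Named genes that changed sign, cause not tested, were as follows. Aars in Acadl Het against wild type was -0.17 within batch 1 and -0.05 to 0.14 leaving out 1 library, and in Acadvl Het -0.04 within batch 2 and -0.03 to 0.05 leaving out 1. Lars2 was 0.08 within batch 1 for the labelled Acadl KO against Acadl Het and -0.11 within batch 1 for Acadvl Het. Psat1 was -0.24 within batch 1 for the labelled Acadl KO against wild type. Acadl in Acadvl Het was 0.04 within batch 1 and -0.04 to 0.01 leaving out 1. In the interaction Acadl was -0.02 within batch 2 and -0.01 to 0.11 leaving out 1, and Acadvl was -0.01 within batch 2 and -0.03 to 0.11 leaving out 1. Over all alternatives, calls of named genes were lost in 58 of 2231 values for the labelled Acadl KO against wild type, 25 of 1699 against Acadl Het, 52 of 2035 for Acadvl KO and 230 of 1331 for the labelled Acadl KO against Acadvl KO. In the same order, 12 of 62, 34 of 46, 20 of 55 and 2 of 36 named genes never lost a call or changed sign. The alternatives include batch 1 alone, with 1 library of some genotypes. Genes with few counts are limited by depth, and in the simulations 22.4% of 1.5-fold interaction terms were recovered among 15661 genes.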

Other observations

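All tests in this part, and the gene lists they use, were chosen only after the result was seen, so the p-values of the lists only restate the counts beside them. Camera p-values are given unadjusted.

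Genes that assemble ribosomes in the nucleolus were higher in the libraries labelled Acadl KO and in Acadvl KO. Of 37 measured, 35 rose in the labelled Acadl KO against wild type (Fisher's exact adjusted p = 3.03e-21, camera p = 0.0154 with an estimated correlation) and 31 in Acadvl KO (adjusted p = 5.07e-21, camera p = 0.0364 with an estimated correlation). Against Acadl Het 35 rose (adjusted p = 4.77e-17, camera p = 0.031 with an estimated correlation). Nop58, a component of small nucleolar ribonucleoproteins, was at 1.05 (SE 0.14) and 0.77 (SE 0.14), and Rrs1 at 0.88 and 0.61. Of 56 cytosolic ribosomal proteins 33 rose in the labelled Acadl KO against wild type, 16 against Acadl Het and 6 in Acadvl KO (adjusted p = 1.2e-09, 1 and 1 by Fisher's exact test, but camera p = 0.271, 0.506 and 0.569 with an estimated correlation). Of 41 translation factors 23, 26 and 12 rose (adjusted p = 2.36e-06, 7.45e-06 and 0.021 by Fisher's exact test, but camera p = 0.141, 0.147 and 0.364 with an estimated correlation). Of 62 mitochondrial ribosomal proteins 29, 31 and 11 rose and 3, 5 and 7 fell (camera p = 0.218, 0.26 and 0.816 with an estimated correlation). Set directly against Acadvl KO, 8 were higher in the labelled Acadl KO (Fisher's exact adjusted p = 7.96e-05, camera p = 0.0861 with an estimated correlation).

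Of 34 cardiac ion channels and receptors, 18 fell and 2 rose in the labelled Acadl KO against wild type, 20 and 2 against Acadl Het, and 15 and 3 in Acadvl KO. In Acadvl KO the adrenergic receptor Adra1a was at -1.31 (SE 0.13) and the potassium channel Kcnd2 at -1.5 (SE 0.24). The list was written after these genes were seen to fall, so no test of it is given, and 4 of its members are also in fixed lists. Targets of the hypoxia-inducible factor, 6 of which are also in fixed lists, went both ways: of 24, 4 rose and 10 fell against wild type, 6 and 10 against Acadl Het, and 4 and 8 in Acadvl KO. Ankrd37 was at -2.76 and -1.77 and Vegfa at 0.87 and 0.46, in the labelled Acadl KO against wild type and in Acadvl KO. Vegfa was not called in Acadvl KO without Acadl Het / Acadvl wt replicate 2 (0.43) or Acadl Het / Acadvl KO replicate 4 (0.38). Ctla4, a lymphocyte receptor on the chromosome of Acadl (60909025 to 60915832), was at -2.17 and -2.18. Of 30 hepatocyte genes 3 rose and 0 fell against wild type, and 0 and 0 in Acadvl KO, where edgeR made the calls, but the median log2 changes were 2.5 and 0.96, each at percentile 100 of 10000 lists matched on expression (camera p = 0.716 and 0.857 with an estimated correlation).

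Asns was higher in Acadl Het hearts without a KO than in wild type, at 2.73 to 7.06 CPM in 7 libraries against 1.22 to 2.13 CPM in 4. The log2 difference was 1.6 (SE 0.409), with an edgeR adjusted p = 0.799 over all genes and an exact permutation p = 0.003 over 330 regroupings for this gene, picked because of it. Within batch 1 the means were 6.15 and 1.33 CPM, and within batch 2 4.43 and 2.09 CPM. A weak integrated stress response with 1 Acadl allele may account for this if the label holds, though Acadl was not lower in Acadl Het / Acadvl wt hearts than in wild type. The other 31 ATF4 targets had a median difference of 0.1, at percentile 100 of 10000 lists matched on expression, but their median per library differed by 0.23 with an exact permutation p = 0.067, so the hypothesis stays open.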
